A study of Mus musculus with 6 samples.

How the data were processed

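RNA from sorted, transduced mouse bone marrow cells was labelled with biotin from 200 ng of total RNA by a whole-transcript sense protocol and hybridised to one-colour Affymetrix arrays, per the labels' protocols. The values analysed are the log2 expression values per probe set that the authors deposited. They were made with RMA, per the submitters' processing notes, a method that corrects background, normalizes probe intensities between arrays and summarises the probes of a set. The version and software, and which arrays were normalized together, are not given in the sources used here. The log2 scale was read from the values, which run from 2.29 to 14.80. RMA pulls dim values together, so fold changes of weakly expressed genes are understated, and no detection call was used. Scanner files were not analysed here.

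All 6 value columns were used and 0 were left out. Of 35557 probe sets, 21789 carry exactly 1 gene symbol in the platform annotation of 2016, 1621 carry several and 12147 are not named in it. Of the single-named probe sets, 21698 matched the mouse gene table by gene ID, and 0 symbols needed an update. Where a gene had several probe sets (999 genes) the one with the highest mean over all 6 arrays was kept, which left 19938 genes. For the named genes with several probe sets, Fbl and Tfdp1, both sets differed in the same direction. No filter on dim probe sets was applied in the main analysis. No genome was used, so no coordinates are given.

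Groups and replicate numbers were taken from the sample titles: 3 MN1 arrays and 3 empty vector arrays. The main test was limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes at default settings, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The residual degrees of freedom were 4 and the estimated prior degrees of freedom 2.43. Differences are MN1 minus empty vector on the log2 scale, and their SE is the moderated one. The model has no block.

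The test, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 22 lists cover the study candidates, stem and progenitor, Hox and Meis, myeloid transcription factor, primary granule, late granulocyte, monocyte, dendritic, erythroid, megakaryocyte, mast and eosinophil, B, T and NK, stromal, cell cycle, p53, interferon, retinoid, Myc, immediate early, cytokine receptor and sex-linked genes. Of 557 list entries, 504 were measured; 19 lie only on probe sets with several names and 34 are not named in the annotation under the symbols used. In all, 11 genes stand in more than 1 list. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 22 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were alternatives. No list was called with an estimated correlation (0 of 22) or by fry (0 of 22, smallest adjusted p 0.24). Of the 10 lists called with the preset correlation, 5 were higher and 5 lower.

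Genes named are Mn1; Cd34, Flt3, Hlf and Dlk1; the 12 with the largest change per direction among genes past the threshold or, since none passed, the 6 with the smallest unadjusted p per direction; and up to 4 members with the largest difference in each list. Immunoglobulin and T cell receptor segments were left out of the third part of the rule.

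The fit was tested on simulated data with the real genes' means and residual spread, in 20 runs of 19938 genes with 200 genes changed, for the comparison of MN1 with empty vector. It called 62.3% of genes changed by 1 on the log2 scale, 89.3% of those changed by 2, 94.7% by 3 and 97.8% by 4, with 184 false calls over all runs. These runs draw each gene's noise independently, which real arrays do not. The shares called also depend on the 200 changed genes, most of them changed by 2 or more, which eases the adjusted threshold. They may not carry over to the real arrays, so an absence of calls there does not show an absence of such changes. Of 200 simulated lists of 25 genes shifted by 0.5, camera called 200, and of 200 unshifted lists it called 3. The genes of these simulated lists also had independent noise, while the correlation estimated within the real lists ran up to 0.67. The rate of false calls therefore does not carry over to the real lists.

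The alternatives were the replicate block, median-centred arrays, quantile normalization, removal of the dimmest 40% of probe sets, the mean of a gene's probe sets, a test of every probe set in the table, an intensity trend with a robust prior, array weights, each array left out in turn, a second threshold of 0.1 and a fold minimum of 2. After seeing the data, list medians were also set against 10000 random lists matched on mean expression, genes were split into 5 bins by mean level, the stem list was tested less the study candidates, and lists called only under an alternative were tested there with an estimated correlation too. Gene families defined by symbol prefix with at least 8 genes were tested with camera as an exploration, and those named were set against random lists matched on expression.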

Results

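Gene expression was measured in mouse bone marrow cells transduced with a retroviral vector carrying MN1, a transcriptional coregulator first identified at a meningioma translocation and often highly expressed in myeloid leukaemia, or with the empty vector. Reporter-positive cells were sorted 72 hours after transduction. Each group held 3 arrays, and the series description states that the transductions were done as 3 independent experiments. The reporter is called GFP in the sample labels and YFP in the series description. The arrays were one-colour Affymetrix whole-transcript arrays with 35557 probe sets, of which 19938 single-named genes were tested. The medians of the 6 arrays lay between 5.82 and 6.01 on the log2 scale. Across genes, which are not independent replicates, the correlation between arrays ran from 0.976 to 0.987 within a group and from 0.966 to 0.992 between groups, so the ranges overlap. On the first principal component, with 36.9% of the variance, the 3 MN1 arrays lay at 45.2, 4.7 and 3.4 and the 3 empty vector arrays at -12.9, -37.1 and -3.4. The second, with 29.2%, did not follow the groups. Empty vector replicate 3 and MN1 replicate 3 lay there at -25.7 and -34.7, and the other arrays at 9.3 to 22.9. The number of arrays, 3 per group, limits the precision of every value below.

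The comparison of MN1 with empty vector asks which genes differ shortly after MN1 is introduced into marrow cells. The transduced gene was higher in every MN1 array: Mn1 measured 6.39 ± 0.28 (SD, n = 3) with MN1 and 5.18 ± 0.33 (SD, n = 3) with the empty vector, a log2 difference of 1.20 ± 0.21 (SE), or 2.3-fold. Its 3 MN1 values, 6.47, 6.62 and 6.08, all lay above the 3 empty vector values of 5.34, 5.41 and 4.80. The adjusted p of Mn1 was 0.584 (limma, Benjamini-Hochberg). The labels do not state the species or extent of the cDNA, so the mouse probe set may read only part of it. By limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.579. At an unadjusted p under 0.05, 832 genes were higher and 843 lower, where 997 in all would be met by chance. After median-centring the arrays, that split was 977 higher and 400 lower. The total was 1675 with all arrays and 906 without empty vector replicate 2, where 508 were higher and 398 lower. The lower genes numbered 475 without MN1 replicate 1 and 488 without MN1 replicate 3. The MN1 and empty vector arrays did not overlap for 16% of genes, where chance gives 10%; MN1 lay above for 1139 of these genes and below for 2052. By size, 198 genes were at least 2-fold higher and 76 at least 2-fold lower.

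None of the genes named below passed adjustment over all genes, so each value is a measured difference and not a call. The 6 genes with the smallest unadjusted p among those higher with MN1 were Ifi203, Mboat2, Cav2, Bmp2, Zfp931 and Vldlr, each with an adjusted p of 0.579. Bmp2, a bone morphogenetic protein, was higher by 2.33 ± 0.30 (SE, log2), and its levels were 7.22 ± 0.51 with MN1 and 4.89 ± 0.36 with the empty vector (SD, n = 3). Vldlr, the very low density lipoprotein receptor, was higher by 2.00 ± 0.27, and Mboat2, a lysophospholipid acyltransferase, by 1.94 ± 0.24. Cav2, which encodes caveolin 2, was higher by 1.41 ± 0.17, and Ifi203, an interferon-inducible gene with close paralogs that a probe set may not tell apart, by 0.97 ± 0.11. The zinc finger gene Zfp931 was higher by 0.62 ± 0.08, at levels of only 4.10 and 3.48. Among genes lower with MN1, the 6 with the smallest unadjusted p were Cemip, Ddc, Rprm, Cytip, Ciita and Siglecf. Cytip, which encodes a cytohesin-binding protein of leukocytes, was lower by 1.09 ± 0.18, with a log2 difference of -1.09 between levels of 8.96 and 10.06. The log2 difference was -0.93 ± 0.11 for Cemip, -0.96 ± 0.13 for the dopa decarboxylase gene Ddc and -0.76 ± 0.11 for Rprm. It was -0.81 ± 0.13 for Ciita, the master regulator of MHC class II genes, and -0.58 ± 0.10 (SE) for the eosinophil receptor gene Siglecf. For all 12 genes the 3 MN1 arrays lay on one side of the 3 empty vector arrays.

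The study's paper is remembered to name 4 genes as MN1-associated, and all of them were higher with MN1 in every array. Dlk1, a Notch-family ligand of progenitor cells, was higher by 2.10 ± 0.52 (SE, log2), or 4.3-fold. Flt3, a receptor tyrosine kinase of early progenitors, was higher by 1.83 ± 0.39, and Hlf, a transcription factor of haematopoietic stem cells, by 1.30 ± 0.43. Cd34, a surface marker of progenitors, was higher by 0.91 ± 0.19, at 11.86 against 10.95. All 4 had an adjusted p of 0.584 over all genes, and all 4 passed when adjusted over the list alone, with adjusted p values of 0.00589 for Cd34 and Flt3, 0.00809 for Dlk1 and 0.0206 for Hlf (limma). The list may have been chosen on these samples, so neither the second count nor a test of the list is independent evidence of its direction. As a list they were higher than other genes (camera adjusted p = 7.84e-06), with an adjusted p = 0.386 with an estimated correlation.

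**Figure D1:**
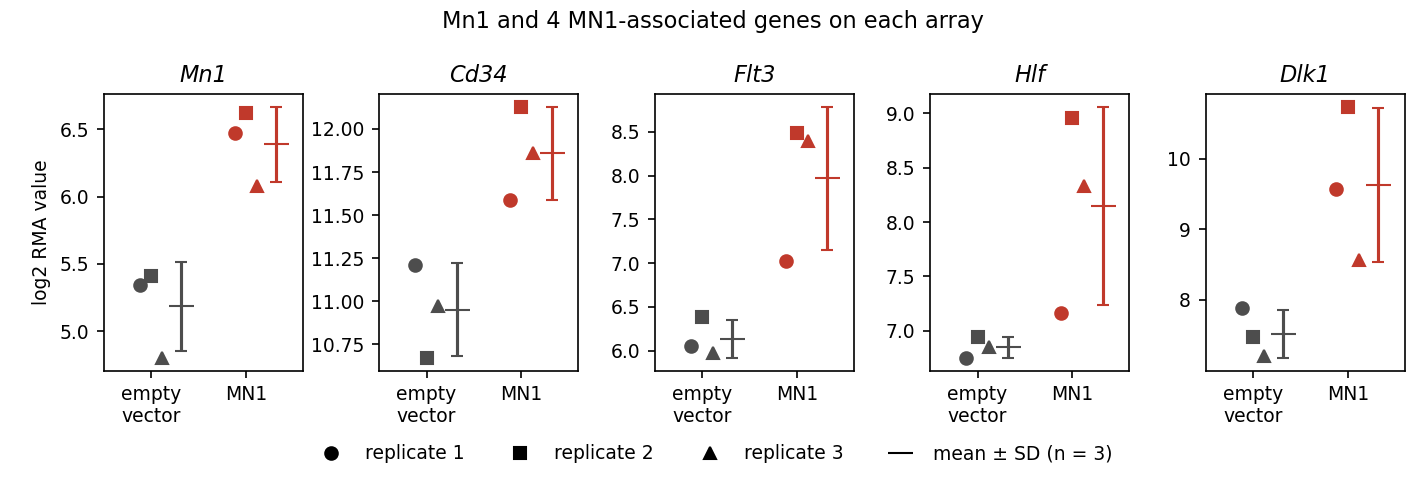
Log2 RMA value (vertical axis, a separate scale for each gene) of Mn1, Cd34, Flt3, Hlf and Dlk1 on each of the 6 arrays, by group (horizontal axis). Symbols mark the replicate number and bars the mean ± SD of 3 arrays; for each gene the 3 MN1 arrays lie above the 3 empty vector arrays.

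Genes of stem and early progenitor cells were on balance higher with MN1. Of 31 measured members, 23 were higher and 8 lower, with a median log2 difference of 0.45. Besides Flt3 and Hlf, the largest differences were in Eng, a TGF-beta coreceptor, at 1.04 ± 0.29 (SE), and Slamf1, the stem cell marker CD150, at 1.04 ± 0.65 with overlapping groups. Adjusted over the list alone, 4 members rose: Flt3, Cd34, Mllt3 and Lmo2. Mllt3, a gene of stem cell maintenance, was higher by 1.01 ± 0.18 and Lmo2, a transcription factor adaptor, by 0.49 ± 0.12; both were named after their values were seen. Adjusted over all genes, none passed, here or in any other list. Camera called the list higher (adjusted p = 3.3e-05), with an adjusted p = 0.386 with an estimated correlation. Its median was 0.28 without empty vector replicate 2 and 0.29 without MN1 replicate 3. Less the 3 study candidates it shares, its median over 28 genes was 0.17 (camera adjusted p = 0.00131), with an adjusted p = 0.386 with an estimated correlation.

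The list of Hox and Meis genes, mostly of the Hoxa and Hoxb clusters, was not called. Of 21 measured members, 7 were higher and 14 lower, with a median of -0.06 (camera adjusted p = 0.726). Meis1, the Hox cofactor, was the exception in size: it was higher by 0.94 ± 0.34 (SE, log2), at 10.04 ± 0.28 against 9.10 ± 0.67 (SD, n = 3), in 3 of 3 arrays. Pbx3 differed by 0.28 ± 0.22, Pknox1 by 0.26 ± 0.14 and Hoxb3 by -0.28 ± 0.10. Of 22 myeloid transcription factors, 10 were higher and 12 lower (camera adjusted p = 0.726), with a median and a mean of -0.03 against a camera direction of higher; the median was 0 after median-centring. Cebpe, which drives granule formation, differed by -0.79 ± 0.58, Maf by 0.68 ± 0.44, Id2 by 0.64 ± 0.27 and Zeb2 by 0.56 ± 0.26. Among 23 cytokine receptors, 8 were higher and 15 lower (camera adjusted p = 0.726), with a median of -0.07 and a mean of 0.02. After Flt3, the largest differences there were -0.75 ± 0.68 in Il1r2, 0.71 ± 0.74 in Il6st and -0.58 ± 0.25 in Cxcr4. The retinoid list had 9 of 21 members higher and 12 lower (camera adjusted p = 0.726), with a median of -0.12 and a mean of 0.03. Dhrs3, a retinaldehyde reductase, was higher by 1.03 ± 0.36 in 3 of 3 arrays, while Dhrs9 differed by 0.74 ± 0.94, Ncf1 by -0.61 ± 0.30 and Rxra by 0.48 ± 0.40.

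Monocyte and macrophage genes were higher with MN1. Of 38 measured members, 31 were higher and 7 lower, with a median log2 difference of 0.56; for 12 of them the 3 MN1 arrays lay above all empty vector arrays and for 0 below. The complement genes C1qa and C1qc were higher by 1.76 ± 0.64 and 1.46 ± 0.58 (SE), the scavenger receptor gene Cd36 by 1.55 ± 0.89 and the glycoprotein gene Gpnmb by 1.45 ± 0.70, the last pair with overlapping groups. None passed when adjusted over the list alone. Against all other genes the list was higher by camera (adjusted p = 1.93e-08), with an adjusted p = 0.386 with an estimated correlation. Its median was 0.37 without MN1 replicate 1.

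All 17 measured megakaryocyte and platelet genes were higher with MN1, with a median log2 difference of 0.78. The platelet chemokine genes Ppbp and Pf4 were higher by 1.34 ± 0.56 and 1.18 ± 0.53 (SE) in 3 of 3 arrays each. Treml1, of platelet granules, differed by 1.19 ± 0.64 and Alox12, the platelet lipoxygenase, by 1.03 ± 0.79, both with overlapping groups. None passed when adjusted over the list alone. By camera the list was higher (adjusted p = 7.97e-05), with an adjusted p = 0.547 with an estimated correlation. The call ended without MN1 replicate 1, where the median was 0.21 (adjusted p = 0.0873). The median was 0.48 without empty vector replicate 2 and 1.22 without MN1 replicate 3.

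Interferon-stimulated genes were higher with MN1. Of 31 measured members, 28 were higher and 3 lower, with a median log2 difference of 0.51. Ifit3, Oasl2 and Mx2, all antiviral effectors, differed by 1.16 ± 0.43, 1.13 ± 0.44 and 1.07 ± 0.55 (SE), and the chemokine gene Cxcl10 by -1.60 ± 0.86; the groups overlapped for each of these 4 genes. None passed when adjusted over the list alone. The list was called higher by camera (adjusted p = 3.22e-08), with an adjusted p = 0.386 with an estimated correlation. Its median was 0.31 without empty vector replicate 2, the array with the lowest mean value of these genes, 8.30.

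Granulocyte genes were on balance lower with MN1, and they varied widely between arrays of the same group. Of 16 primary granule genes, 15 were lower and 1 higher, with a median log2 difference of -0.66. Of 30 genes of late granulocytes, 25 were lower and 5 higher, with a median of -0.93. Among primary granule genes, Ms4a3 differed by -1.75 ± 1.10 (SE), the ficolin gene Fcnb by -1.63 ± 0.91, neutrophil elastase (Elane) by -1.59 ± 1.99 and proteinase 3 (Prtn3) by -1.30 ± 1.18. Elane ran from 6.45 to 12.96 over the 3 empty vector arrays and from 6.98 to 11.68 over the 3 MN1 arrays. Among late genes, the stefin gene Stfa3, which has close paralogs, differed by -1.91 ± 1.87, the neutrophil marker gene Ly6g by -1.83 ± 1.30, Retnlg by -1.34 ± 1.30 and the calgranulin gene S100a8 by -1.32 ± 0.63. The groups overlapped for each of these 8 genes, and no member of either list passed when adjusted over the list alone. Camera called both lists lower, at an adjusted p = 0.0029 for primary granules and 0.00501 for late granulocytes; both had an adjusted p = 0.547 with an estimated correlation. Both calls ended without empty vector replicate 2, with medians of -0.42 (adjusted p = 0.0791) and -0.35 (adjusted p = 0.162). Without MN1 replicate 1 the medians were -0.42 and -0.56.

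Genes of mast cells, basophils and eosinophils were also lower with MN1. Of 26 measured members, 22 were lower and 4 higher, with a median log2 difference of -0.68. The ribonuclease gene Ear6, which has close paralogs, differed by -1.97 ± 0.78 (SE), the lipoxygenase gene Alox15 by -1.76 ± 0.44, the basophil protease gene Prss34 by -1.54 ± 1.65 and Prg2, eosinophil major basic protein, by -1.46 ± 0.95. Of these only Alox15 had non-overlapping groups. Adjusted over the list alone, 1 member fell, Siglecf, at an adjusted p of 0.0209 (limma). The list was called lower by camera (adjusted p = 3.35e-05), with an adjusted p = 0.386 with an estimated correlation. Its median was -0.31 without MN1 replicate 1.

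**Figure D2:**
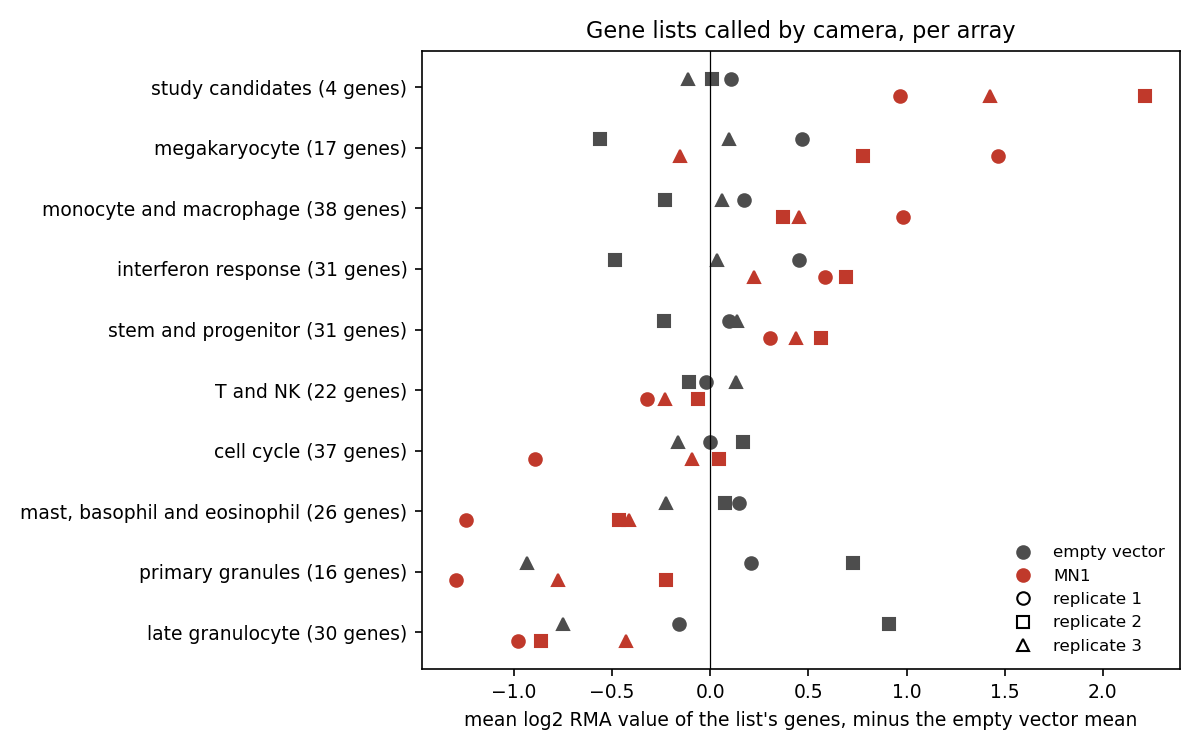
Mean log2 RMA value of each gene list called by camera, per array, minus the mean of the 3 empty vector arrays (horizontal axis), with 1 row for each of 10 lists and the number of measured genes in brackets. Colours mark the group and symbols the replicate number. MN1 and empty vector arrays separate for the study candidate, stem, monocyte and mast lists and overlap for the other 6.

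Of the markers of other cell types that the sorted marrow could hold, those of T and natural killer cells were lower. Of 22 measured, 17 were lower and 5 higher, with a median log2 difference of -0.25 at a mean level of only 5.93. Thy1 differed by -1.10 ± 0.59 (SE), Prf1 by 0.73 ± 0.57, Cd2 by -0.67 ± 0.45 and Cd8a by -0.43 ± 0.12. The list was called lower by camera (adjusted p = 0.00477), with an adjusted p = 0.386 with an estimated correlation. The call ended without empty vector replicate 3, where the median was -0.14 (adjusted p = 0.0518).

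The other cell type lists were not called with all arrays. Of 21 B lineage genes, 12 were higher and 9 lower (median 0.13, camera adjusted p = 0.191). They were called higher without empty vector replicate 3 (median 0.61, adjusted p = 0.000267) and without MN1 replicate 2 (median 0.48, adjusted p = 0.000357), with an adjusted p = 0.506 and an adjusted p = 0.479 with an estimated correlation. The median was -0.21 without empty vector replicate 2. The mean of these genes was 6.51 to 7.13 on empty vector replicate 3 and MN1 replicates 1 and 3, and 5.58 to 5.89 on the other arrays. That follows the Y-linked genes described below and not the groups, so the gained calls may not reflect MN1. Il7r differed by 1.5 ± 0.73 (SE), Blnk by 1.08 ± 0.74, Dntt by 0.88 ± 0.36 and Igll1 by 0.75 ± 0.40. Of 21 dendritic cell and antigen presentation genes, 10 were higher and 11 lower, with a median of 0.00, a mean of -0.17 and a median of 0.03 after median-centring (camera adjusted p = 0.417). The chemokine genes Ccl22 and Ccl17 differed by -1.56 ± 0.52 and -1.55 ± 0.88, Itgax by 1.06 ± 1.08 and Ccr7 by -0.88 ± 0.62. Adjusted over the list alone, 1 member, Ciita, fell. Camera called the list lower without MN1 replicate 1 (median -0.30, adjusted p = 0.0276), with an adjusted p = 0.623 with an estimated correlation. Of 27 erythroid genes, 9 were higher and 18 lower (median -0.18, camera adjusted p = 0.217). The carbonic anhydrase gene Car1 differed by -1.24 ± 0.43, Rhag by -1.10 ± 0.43, Klf1 by -0.64 ± 0.27 and Ermap by -0.59 ± 0.20, each lower in 3 of 3 arrays. Of 21 stromal and endothelial genes, 9 were higher and 12 lower, with a median of -0.02, a mean of 0.01 and a median of 0.01 after median-centring or quantile normalization (camera adjusted p = 0.517). Kdr, a VEGF receptor gene, was higher by 1.74 ± 0.68, while Acta2 differed by -0.46 ± 0.15, Col6a1 by -0.35 ± 0.15 and Col1a1 by -0.34 ± 0.12.

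Genes of DNA replication and mitosis were slightly lower with MN1: 34 of 37 were lower and 3 higher, with a median log2 difference of -0.38. Rrm2 differed by -0.66 ± 0.41 (SE), Plk1 by -0.55 ± 0.53, Kif20a by -0.54 ± 0.42 and Ccnb2 by -0.53 ± 0.36, all with overlapping groups. Camera called these genes lower (adjusted p = 0.00341), with an adjusted p = 0.862 with an estimated correlation. The call ended without MN1 replicate 1, where the median was -0.03 (adjusted p = 0.895). Among 22 p53 targets and cell death genes, 14 were higher and 8 lower, with a median of 0.16 and a mean of 0.00 (camera adjusted p = 0.528), or 0.31 without empty vector replicate 3, where camera called the list (adjusted p = 0.0224), with an adjusted p = 0.506 with an estimated correlation. Perp, an apoptosis effector, differed by -1.20 ± 0.23 and was the 1 member that fell when adjusted over the list alone, at an adjusted p of 0.0348 (limma). Cdkn2b, a cell cycle inhibitor, differed by -0.94 ± 0.25, Bcl2l11 by -0.74 ± 0.68 and Zmat3 by 0.61 ± 0.49. Of 27 Myc and ribosome biogenesis genes, 9 were higher and 18 lower (median -0.05, camera adjusted p = 0.781); Tfdp1 and Fbl differed by -0.24 ± 0.20 and -0.24 ± 0.16, and Cad and Srm by -0.19 ± 0.34 and -0.19 ± 0.25. Camera called that list lower without empty vector replicate 2 (median -0.15, adjusted p = 0.0365) and without MN1 replicate 2 (median -0.19, adjusted p = 0.0403), with an adjusted p = 0.817 and an adjusted p = 0.601 with an estimated correlation. Of 22 immediate early and heat shock genes, 11 were higher and 11 lower (median 0.04, camera adjusted p = 0.227). They were called higher without MN1 replicate 2 (median 0.31, adjusted p = 0.00106) and without empty vector replicate 3 (median 0.18, adjusted p = 0.0342), with an adjusted p = 0.479 and an adjusted p = 0.581 with an estimated correlation. The mean of these genes was at least 9.72 on empty vector replicate 3 and MN1 replicates 1 and 3, and at most 9.58 on the other arrays. That also follows the Y-linked genes described below and not the groups. Trib3 differed by 0.72 ± 0.72, Ddit3 by 0.68 ± 0.27, Fosb by 0.59 ± 1.09 and Egr1 by 0.54 ± 0.55.

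Sex-linked genes, read as a check of the donors, varied widely between arrays of the same group. The Y-linked gene Eif2s3y measured 3.43 on empty vector replicate 2 and between 6.72 and 8.57 on the other 5 arrays. Uty measured 3.69 and Kdm5d 4.21 on that array, the lowest of the 6 in each case, and Xist, the X-inactivation RNA, was highest there at 10.25 against 8.70 to 9.79 elsewhere. After that array, empty vector replicate 1 and MN1 replicate 2 had the lowest values of all 3 Y-linked genes. The group differences were 1.83 ± 1.18 (SE) for Eif2s3y, 1.52 ± 0.85 for Uty, 0.86 ± 0.47 for Kdm5d and -0.07 ± 0.40 for Xist (camera adjusted p = 0.081 for the list of 4); the groups overlapped for each gene. The list was called higher with an intensity trend (adjusted p = 0.0455) and without empty vector replicate 3 (median 1.79, adjusted p = 0.0277), with an adjusted p = 0.35 and an adjusted p = 0.425 with an estimated correlation. It was also called with the replicate block (camera adjusted p = 0.00376), with an adjusted p = 0.701 with an estimated correlation. Empty vector replicate 2 also had the highest mean of the late granulocyte genes, 10.85, and the lowest means of the megakaryocyte, monocyte, stem and interferon genes.

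**Figure D3:**
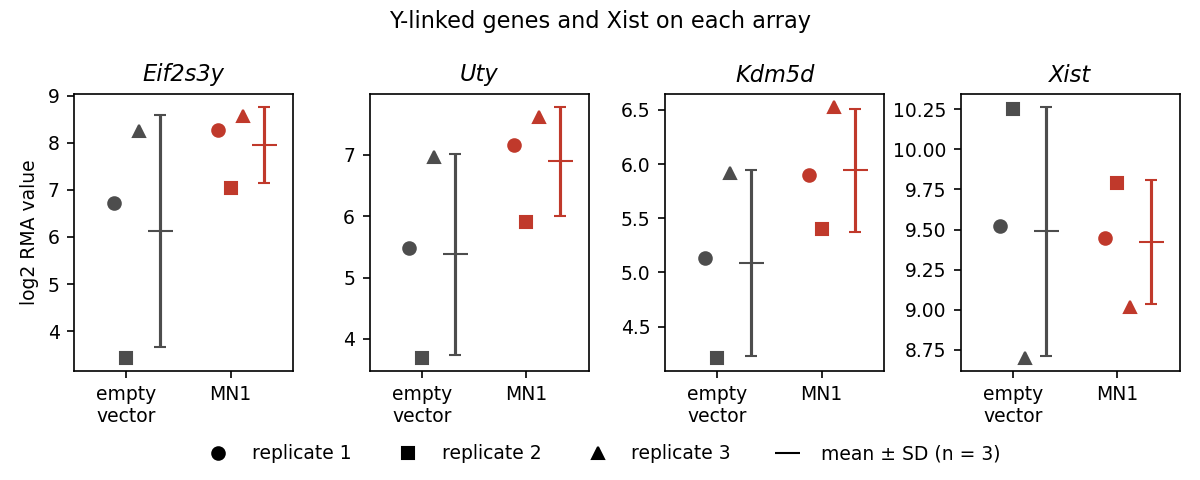
Log2 RMA value (vertical axis, a separate scale for each gene) of the Y-linked genes Eif2s3y, Uty and Kdm5d and of Xist on each array, by group (horizontal axis); symbols mark the replicate number and bars the mean ± SD of 3 arrays. Empty vector replicate 2 has the lowest value of each Y-linked gene and the highest of Xist.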

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

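The stem list less the study candidates (median 0.17) was chosen after the results were seen. So were the tests, with an estimated correlation, of lists called only under an alternative. The other alternatives in this section were set in advance. The counts of 0 genes higher and 0 lower at an adjusted p under 0.05 by limma (832 and 843 at an unadjusted p under 0.05) held under each alternative, including the replicate block, the threshold of 0.1 and each array left out. Mn1 stayed higher, by 1.01 to 1.36 on the log2 scale, with adjusted p values from 0.428 to 0.935. At unadjusted p under 0.05, the lower genes numbered 400 after median-centring and 369 with dim probe sets removed, against 843; testing every probe set gave 1287 higher and 1270 lower probe sets out of 35557, which is more tests. Leaving out 1 array gave 508 to 1044 higher and 398 to 1037 lower genes, lowest in both cases without empty vector replicate 2; without MN1 replicate 1 and without MN1 replicate 3 the lower genes were 475 and 488. The cause of these moves was not tested, apart from the number of tests. The 10 list calls became 0 with an estimated correlation and 0 by fry, and were 9 to 13 with 1 array left out; all 10 kept their direction in the 16 other settings in which lists were tested. With the replicate block, 1140 genes were higher and 840 lower at unadjusted p under 0.05, and 11 lists were called, the 10 and the sex-linked list. The sex-linked list had a camera adjusted p = 0.00376 there at the preset correlation and 0.701 with an estimated one. Deviations of same-numbered arrays from their group means correlated at 0.13, 0.07 and 0.32, not each above 0.1, and not every array correlated best with its own number: empty vector replicate 1 and MN1 replicate 2 reached 0.44. Over 97 named genes, 1346 of 1355 alternative values kept direction and 9 reversed. No gene passed the threshold in any setting, so the side of the threshold could not have changed. Most named genes were picked for small p values or large differences on these same arrays, so their kept direction is little evidence. Over the lists, 298 of 353 values kept direction and side of the threshold, 25 lost the threshold, 11 passed it and 19 reversed.

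Lists with medians near 0 changed sign. Median-centring gave medians of 0 for myeloid transcription factors, 0.03 for dendritic genes and 0.01 for stroma, quantile normalization 0.01 for stroma, dim probe sets removed 0.06 for retinoid genes, and every probe set 0.01 for dendritic and -0.01 for immediate early genes. With 1 array left out, medians ran from -0.12 to 0.01 for Hox and Meis, -0.29 to 0.17 for myeloid transcription factors, -0.21 to 0.61 for B lymphoid, -0.19 to 0.07 for Myc, -0.13 to 0.31 for immediate early and -0.12 to 0.01 for cytokine receptor genes. The same fits gave log2 differences from -0.29 to 1.69 for Dhrs9, -0.01 to 0.73 for Rxra, -0.54 to 0.15 for Cad, -0.40 to 0.02 for Srm, -0.14 to 1.40 for Trib3, -0.14 to 1.74 for Fosb and -0.46 to 0.31 for Xist. The cause was not tested. Without a detection call, how far dim values limit a result could not be set.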

Other observations

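Tests of single-array and distribution explanations, of the neutrophil-lineage share, of dim values and of families against matched lists and scalings were chosen or given their final bounds after the values they bear on were seen; the counts over splits and the monocyte test were set before.

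Beyond the fixed lists, 309 gene families sharing a symbol prefix were tested as an exploration, and camera called 40 of them at the preset correlation, 21 higher and 19 lower, and 0 with an estimated correlation (smallest adjusted p 0.659). The schlafen genes (Slfn), growth regulators inducible by interferon, had a median log2 difference of 0.68 over 9 genes, of which 8 were higher and 1 lower. Slfn1, Slfn5 and Slfn4 were higher by 1.32 ± 0.37, 1.13 ± 0.26 and 1.12 ± 0.33 (SE). The guanylate-binding protein genes (Gbp) had a median of 0.70 over 8 genes, and the Toll-like receptor genes (Tlr) 0.57 over 10 genes. Tlr7 was higher by 1.25 ± 0.29, Tlr13 by 1.11 ± 0.36 and Tlr3 by 0.84 ± 0.14, while Tlr9 differed by -0.52 ± 0.43. The Vps genes of vesicle sorting had a median of 0.17 over 35 genes, at the upper limit of 0.17 of random lists matched on expression, and 0.09 after quantile normalization. Schlafen and guanylate-binding genes have close paralogs, so the values of single members are uncertain.

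Among families that were lower, the collagen genes (Col) had the smallest adjusted p of the scan, 4.16e-06 by camera, with a median log2 difference of -0.21 over 44 genes, of which 41 were lower and 3 higher; with an estimated correlation its adjusted p = 0.66. Among homeobox families, these 4 were called lower by camera at the preset correlation: the median was -0.20 over 9 Hoxc genes, -0.21 over 10 Hoxd genes, -0.20 over 13 Nkx genes and -0.23 over 8 Lhx genes, each with an adjusted p = 0.659 with an estimated correlation. It was -0.21 over 19 Wnt genes, -0.19 over 21 Sox genes, -0.12 over 52 keratin genes (Krt) and -0.14 over 44 keratin-associated genes (Krtap). The mean level of these 8 families and the collagen genes lay between 4.89 and 6.38, where most genes were slightly lower with MN1. Random lists matched on expression had medians down to -0.14 for the collagen genes, -0.20 for Hoxc, -0.20 for Hoxd, -0.21 for Nkx, -0.22 for Lhx, -0.18 for Wnt, -0.17 for Sox, -0.15 for Krt and -0.12 for Krtap at their lower limit. Median-centring and quantile normalization left the sign of the median of all 13 families named here as it was.

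With 3 arrays per group there are 10 splits, too few for a share under 0.05. The real split gave 1675 genes at an unadjusted p under 0.05 and the highest other split 2327, and 2 of the 10 splits gave at least as many as the real one. At an adjusted p under 0.05 the real split gave 0 genes and the highest other split 13, and 10 of the 10 gave at least as many. For lists called by camera the real split gave 10, the lowest other 7 and the highest other 12, and 4 of the 10 gave at least as many. The split with 2327 genes set empty vector replicates 1 and 2 with MN1 replicate 2 against the rest. Empty vector replicates 1 and 2 and MN1 replicate 2 had the lowest values of Eif2s3y, Uty and Kdm5d and the highest of Xist, which was noticed after the splits were run.

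Stem, monocyte and megakaryocyte genes were higher while granulocyte and mast genes were lower. After quantile normalization the 6 signed medians kept 0.983 of their mean size. The 6 lists stayed called at the preset correlation, although 0 lists are called with an estimated one or by fry. RMA had already normalized the arrays, whose medians lay between 5.82 and 6.01. What differences remained between their distributions could hardly take the list medians under the bound of 0.5. No conclusion on the arrays' distributions is therefore drawn from that test. A smaller share of neutrophil-lineage cells with no other change would leave other cell types higher. The mast list's median was -0.68 against an SE of 0.29, or -0.31 against 0.12 without MN1 replicate 1. These values go against that explanation but do not exclude it. The bound was only the SE itself, and the list had a camera adjusted p = 0.386 with an estimated correlation. Of the mast members named above, Ear6, Prss34 and Prg2 were highest on the same arrays as Elane, and Alox15 was not. The mast list also holds eosinophil and basophil genes, so its values do not bear on the share of granulocytes as a whole. That share was not tested. For the late granulocyte list, empty vector replicate 2 alone is a candidate explanation: without it the median went from -0.93 to -0.35, under 0.5 of its size. For primary granules it went from -0.66 to -0.42, over 0.5 of its size, and was also -0.42 without MN1 replicate 1. That array alone is therefore left open for primary granules. The medians of both lists together kept 0.484 of their size, just under the bound of 0.5, with a spread of 0.47. Empty vector replicates 1 and 2 and MN1 replicate 2, the arrays with the lowest Y-linked values, also had the highest means of primary granule genes. These were 11.04, 11.56 and 10.61, against 9.54 to 10.06 on the others. Late granulocyte genes did not follow that split, and its effect on either list was not tested. Without empty vector replicate 2 the other 4 lists stayed called at the preset correlation. The share of 0.982 for monocyte genes passed the bound of 0.5 by more than the spread, which argues against that array alone. The share of 0.985 for mast genes did not. However, the mast median without that array was -0.67, with a spread of 0.33, against -0.68 with all arrays. Its mast score of 9.49 lay between those of empty vector replicates 1 and 3, 9.56 and 9.19, which both exceeded every MN1 array. These values argue against that array alone for the mast list too. The shares of 0.622 for stem and 0.615 for megakaryocyte genes did not pass the bound by more than the spread and leave it open. An untested effect of MN1 on differentiation also stays open.

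Interferon genes were higher with MN1. The list's median lay at percentile 100 of 10000 random lists matched on expression and exceeded their upper limit of 0.14 by more than its SE of 0.31. This was no test of a fall of dim values, which would not raise a list with a mean level of 9.04. The random lists also lack the correlation between the list's genes, estimated at 0.37, so no conclusion is drawn from the percentile. More monocyte-like RNA, which the reporter sort would not remove, is a candidate explanation: the interferon score minus the monocyte score differed between groups by -0.10 ± 0.27 (SE) and the lists share 0 genes. That test had little power. Only a difference beyond 2 SE would have argued against the explanation, and the interferon score itself differed by 0.50. Of the bright monocyte genes, Ctsd (13.66 with MN1, 13.12 with the empty vector) was higher by 0.54 ± 0.18, while Lyz2 (13.25 and 13.13) differed by 0.12 ± 0.26 with overlapping groups and gives no support. Of the list's 38 members 31 were higher, but the monocyte genes Cx3cr1, Cd14 and Ccr2 differed by -0.38 ± 0.22, -0.36 ± 0.57 and -0.10 ± 0.61. The empty vector arrays ranked alike on the monocyte and interferon scores, but the MN1 arrays did not. Of these, MN1 replicate 2 had the lowest monocyte score, 10.6, and the highest interferon score, 9.48. Without MN1 replicate 1 the monocyte median fell from 0.56 to 0.37, while the interferon median was 0.58. Left open is empty vector replicate 2 alone, without which the median kept 0.608 of its size. For 1 MN1 array alone the lowest share kept was 0.941. The list stayed called at the preset correlation without each of these arrays, but neither share exceeded the bound of 0.5 by more than its spread, 0.25 and 0.33. However, without MN1 replicates 1, 2 and 3 in turn the median was 0.58, 0.48 and 0.63, against 0.51 with all arrays. The lowest of these, 0.48, exceeded its spread of 0.33. The MN1 interferon scores, 9.37, 9.48 and 9.01, all exceeded those of empty vector replicates 2 and 3, 8.3 and 8.82. These values argue against 1 MN1 array alone, although empty vector replicate 1, at 9.24, lay above MN1 replicate 3. An effect of MN1 itself also stays open and untested.

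T and natural killer genes were lower at a mean level of 5.93, and dim genes as a whole were lower with MN1. The median log2 difference was -0.12 in the second of 5 bins by mean level, where 79.4% of genes were lower, and 0.11 in the fourth. In the third, which holds the list's mean level, it was -0.048, and 56% of genes were lower. The list's median of -0.25 lay at percentile 0 of the random lists matched on expression, but passed their lower limit of -0.16 by less than its SE of 0.10. A general fall of dim values therefore stays open for this list, because the excess is within its spread.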
